A study of Mus musculus with 6 samples.

How the data were processed

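RNA-seq was made from 6 libraries of mouse cardiomyocytes that were differentiated in culture from an embryonic stem cell line (E14 carrying an Nkx2-5-EmGFP transgene, a reporter of the cardiac gene Nkx2-5), per the labels. Cells were transduced with lentivirus on day 8 and collected on day 10, per the labels' protocols. The virus carried either pLKO, the control vector, or a short hairpin RNA against Lmna, the gene of the nuclear lamins A and C. Polyadenylated RNA was sequenced, per the labels. The submitters' processing notes name STAR, DESeq2, edgeR and the mm10 build, with no version or role, and the read counter, the strand setting and the sequence of the hairpin are not given in the sources used here.

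The groups came from the sample titles and source names, with 3 libraries of Lmna shRNA and 3 of control pLKO. The genotype entry of the labels says the opposite: it calls the libraries titled as knockdown wild type and those titled pLKO Lmna knockdown. The level of Lmna in every library is given first in the results as a check of that conflict. Nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between these libraries, which may be technical.

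The deposited table holds 30718 RefSeq transcripts. Its count columns are whole numbers of reads per transcript as the authors deposited them, per the file headers, with no normalization. Reads in exons that isoforms share appear in the count of each isoform: among the 6843 genes with several transcripts, the median ratio of the lowest to the highest isoform count was 0.963. A second block of columns, named TMM per the file headers, is a signal that the authors made by dividing each library's counts by one constant, and its mean over the 6 libraries equals the deposited mean of a DESeq2 result. The deposited RPKM columns equal the counts scaled by transcript length and by the column total. The authors also deposited a log2 fold change with its standard error, a score (the Wald statistic, and a mean of scaled counts) and p-values with their adjusted form, under DESeq2's names per the file headers. The smallest deposited mean of scaled counts was 3.38, so transcripts below about that level were not analysed here.

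In 1481 transcripts the gene name read 0.000; 1479 of them were named through their accession from a RefSeq table of the GRCm38.p6 assembly, and 2 kept the accession. Gene coordinates come from the same table. For each of 15762 genes, the transcript with the most reads was used, a choice made after the structure of the table was seen. This avoids counting shared reads more than once. Totals per library over these genes ran from 14382103 to 16152598, and over all transcripts, where shared reads repeat, from 30845016 to 34516850.

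The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on these counts, with TMM scaling, the filterByExpr filter, group as the only term and Benjamini-Hochberg adjustment at 0.05. It tested 14270 genes, and every adjusted p for a gene is from it unless another tool is named. Log2 fold changes are Lmna shRNA over pLKO with their standard error (SE), and levels are in CPM, counts scaled to a common library total after TMM, as mean ± SD over 3 libraries per group. Counts were simulated for these 14270 genes with the means and library sizes of this comparison. Genes to change were drawn only from those with a mean of at least 5 CPM. Of them the test called 18 of 67 changed by 1.5-fold, 59 of 67 changed by 2-fold and 66 of 66 changed by 4-fold. It also called 7 unchanged genes. Recovery of changes at lower levels was not simulated. The biological coefficient of variation was 14.9%.

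Before the data were examined, 36 gene lists, the design, the alternatives and the rule for naming genes were fixed. The lists cover the nuclear lamina and envelope, sarcomere, calcium handling and excitation, cardiac transcription factors, atrial and ventricular chambers, S phase, G2 and mitosis, p53 targets, type I interferon response, inflammation, the integrated stress response, the unfolded protein response, cardiac stress, immediate early genes, targets of YAP and SRF, TGF-beta and Wnt, the Notch pathway, fatty acid oxidation, oxidative phosphorylation, glycolysis, hypoxia, cholesterol synthesis, markers of endothelial, smooth muscle, fibroblast, epicardial, endoderm, neural, pluripotent, blood and skeletal or early mesoderm cells, mitochondrially encoded genes, reference genes and ribosomal proteins. No mitochondrially encoded gene was in the table, which left 35 lists. Each was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way without a comparison with other genes, were alternatives.

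The text names Lmna, then the 12 genes with the largest change each way among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes, and then up to 4 members of each list with the smallest adjusted p. Genes named outside this rule are said to be so. Alternatives were DESeq2's size factors, library size alone, no count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p of 0.01 and leaving out each library. The longest transcript per gene, the sum over transcripts and every transcript on its own were added after the table was seen. The alternatives of pseudocount and of a filter on low normalized values did not apply, because counts were present.

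No pair of libraries was counted as a repeat: the chi-square per degree of freedom between replicate counts ran from 6.98 to 35.7. Genes with near-identical copies, such as ribosomal protein, keratin and glycolytic genes with processed pseudogenes, depend on how the authors' counter treated reads with several matches. Without a stated strand setting, reads of overlapping genes cannot be assigned with certainty. Copies, 3' UTRs and lengths were taken from the GENCODE M21 annotation and transcripts, and copies were searched with BLAST 2.17.0.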

Results

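Gene expression was measured by RNA-seq of polyadenylated RNA in mouse cardiomyocytes that had been differentiated from embryonic stem cells and transduced on day 8. Cells were collected on day 10, with 3 libraries of cells given a short hairpin RNA (shRNA) against Lmna and 3 of cells given the pLKO control vector. Total counts over 1 transcript per gene ran from 14382103 to 16152598 per library. The share of counts taken by Igf2, the most abundant gene, ran from 3.36% to 6.33%. Correlations of log2 CPM lay between 0.981 and 0.991 within groups and between 0.943 and 0.963 between groups, and the first principal component held 68.0% of the variance. The comparison asks which transcripts differ when Lmna is knocked down in cultures that the labels call cardiomyocytes. The share of cardiomyocytes in them was not measured here.

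Lmna encodes lamins A and C, intermediate filament proteins that line the inner nuclear membrane. It was read first because the genotype entry of the labels contradicts the titles. Lmna (NM_001002011; chromosome 3, 88481148 to 88509932, minus strand, GRCm38, protein coding) fell from 857 ± 71.0 CPM with pLKO to 34.8 ± 6.54 CPM with Lmna shRNA (SD, 3 libraries each). The log2 fold change was −4.62 with an SE of 0.17 (edgeR adjusted p = 7.59e-07). Counts were 14345, 13966 and 11929 in the libraries titled pLKO and 487, 435 and 636 in those titled knockdown. The other Lmna transcripts had 8733 to 10547 and 6017 to 8244 reads with pLKO, against 254 to 379 and 193 to 314 with Lmna shRNA. Lmna was thus low in every library that the titles call knockdown, and all directions here follow the titles, against the genotype entry. In the authors' deposited table the log2 fold change of Lmna was −4.60. Of the other lamin genes, named outside the naming rule, Lmnb2 rose by 0.36 (edgeR adjusted p = 0.0327), a call lost without Lmna_shRNA replicate 2 or any single control (up to 0.0977), and Lmnb1 had a log2 fold change of −0.22 (edgeR adjusted p = 0.126).

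**Figure D1:**
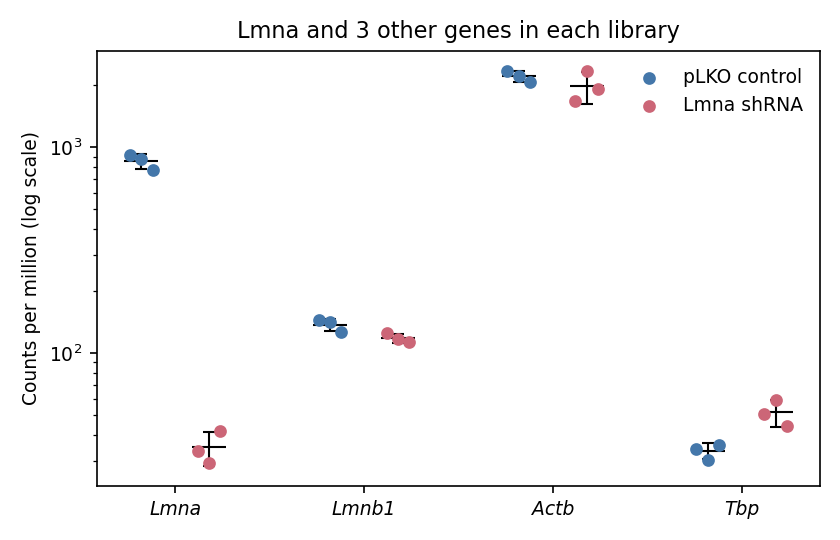
Normalised counts (CPM, log axis) of Lmna, Lmnb1, Actb and Tbp in each library; blue points are pLKO controls, red points are Lmna shRNA libraries, and black bars give the mean and SD of 3 libraries. The Lmna shRNA libraries lie between 29.2 and 42.0 CPM for Lmna and the pLKO libraries between 778 and 916 CPM.

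Beyond Lmna, and among genes with a mean of at least 5 CPM, leaving out predicted genes, the largest rises in Lmna shRNA libraries were in Lonrf2 (log2 fold change 3.01 ± 0.35 SE), Ripk4, a kinase of epidermal differentiation (2.57 ± 0.32), Wfikkn1 (2.35 ± 0.28) and Sgk1, a serum- and glucocorticoid-regulated kinase (2.33 ± 0.22). Sgk1 went from 17.7 ± 2.83 to 88.7 ± 26.6 CPM. They were followed by Lfng, a glycosyltransferase that modifies Notch receptors (2.15), the epithelial keratin gene Krt7 (2.09), the death receptor gene Tnfrsf21 (2.00), Spef1 (1.98), Amigo2 (1.95), Gpt, an alanine aminotransferase (1.93), the metallothionein gene Mt2 (1.90) and Aoc2 (1.90). Krt7 rose from 28.4 ± 2.03 to 121 ± 44.6 CPM and Tnfrsf21 (chromosome 17, 43016555 to 43089188) from 34.3 ± 1.66 to 137 ± 17.9 CPM. The largest fall among such genes was in Ndufa4l2, a hypoxia-inducible relative of a respiratory chain subunit (chromosome 10, 127509274 to 127517154), from 82.5 ± 15.9 to 1.02 ± 1.06 CPM (−6.32 ± 0.42 SE). Lpl, lipoprotein lipase (chromosome 8, 68880555 to 68906932), fell from 298 ± 20 to 33.9 ± 4.02 CPM (−3.14 ± 0.13 SE). Slc16a3, a lactate exporter (chromosome 11, 120948484 to 120959000), fell from 295 ± 32.9 to 38.3 ± 17.9 CPM. Acod1, the enzyme that makes itaconate (−3.39), G0s2, an inhibitor of fat lipase (−3.36), Serpinb2 (−3.16), Lrrc55 (−3.02), Srpx2 (−2.94), F2rl2 (−2.90), the chemerin receptor gene Cmklr1 (−2.90) and Emp2 (−2.88) also fell. Among these 23 genes the edgeR adjusted p ran from 1.68e-06 for Lpl to 0.00256 for Mt2, and the groups did not overlap. Both a passing adjusted p and the lack of overlap were conditions of the naming rule. Some overlap other annotated genes, named here outside the naming rule, whose reads the counting may have mixed in. Ndufa4l2 overlaps Shmt2 (−0.43), Amigo2 overlaps Pced1b (0.54), Slc16a3 overlaps Csnk1d (0.28) and F2rl2 overlaps Iqgap2 (−0.87). Pced1b was not called (edgeR adjusted p = 0.0516). Csnk1d was called at an edgeR adjusted p of 0.0457, which rose to 0.154 without control_pLKO replicate 2. Its call was lost in 5 of 6 fits with 1 library left out. Sgk1, Acod1 and Cmklr1 overlap predicted genes.

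**Figure D2:**
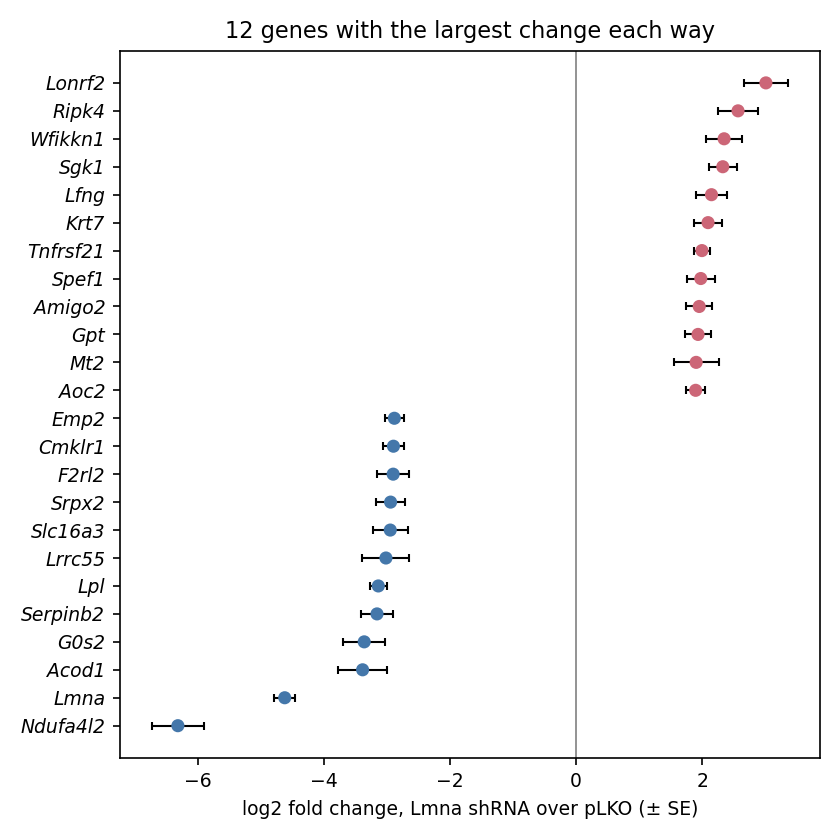
Log2 fold change (Lmna shRNA over pLKO, edgeR) of the 12 genes with the largest change each way under the naming rule; points are estimates and bars are ± 1 SE, with higher genes in red and lower genes in blue. Values run from 3.01 for Lonrf2 to −6.32 for Ndufa4l2, with Lmna at −4.62.

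Of 14270 genes tested with edgeR, 2752 were higher and 3060 lower with Lmna shRNA, and 8458 did not pass the adjusted threshold. At least 2-fold changes were found for 568 higher and 1181 lower genes. The groups did not overlap in 7507 genes (52.6%, where chance gives 10%). The count of higher genes fell to 1665 without control_pLKO replicate 2. The authors' deposited table called 5929 of the tested genes, 5622 of which were among the 5812 called here, all with the same sign.

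**Figure D3:**
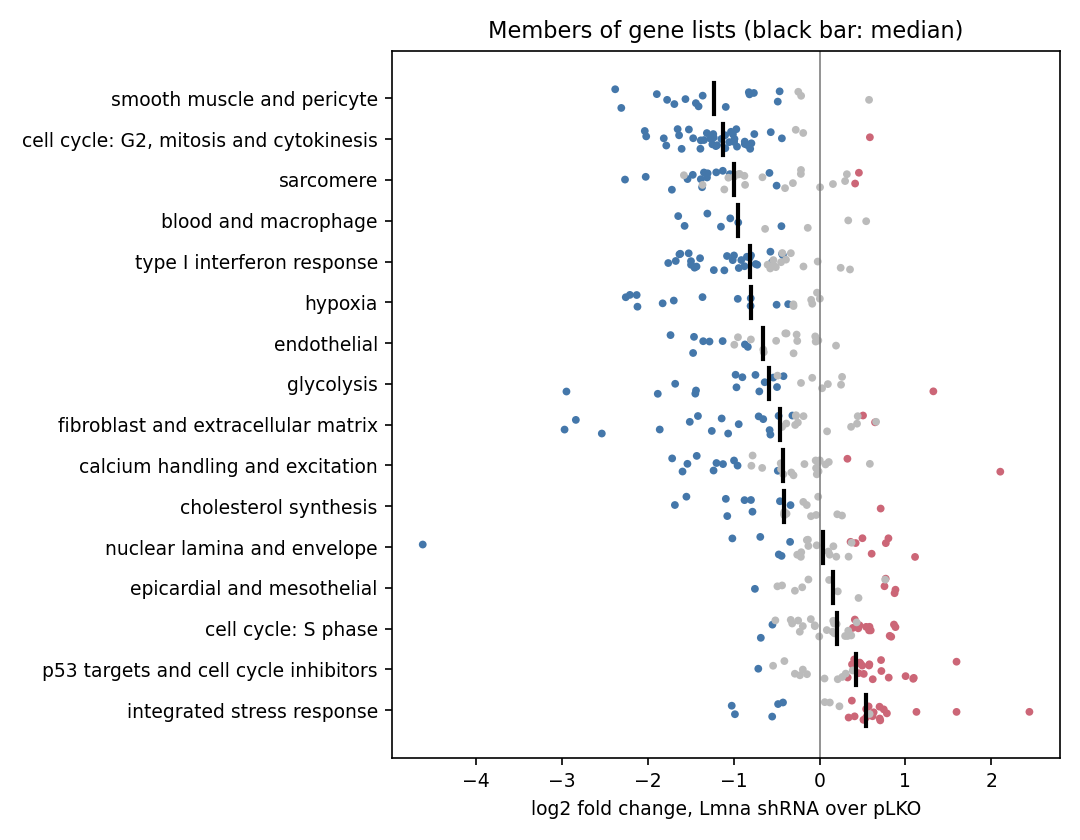
Log2 fold change (Lmna shRNA over pLKO, edgeR) of every tested member of 16 of the gene lists; red and blue points are members higher or lower at an edgeR adjusted p under 0.05, grey points did not pass, and each black bar is the list's median. Medians run from −1.23 for the smooth muscle and pericyte list to 0.54 for the integrated stress response list.

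Of the 35 lists tested, 14 differed from the other genes with camera at its preset correlation. None did with an estimated correlation. Other divisions of the same 6 libraries into 3 and 3, all of which mix the groups, called up to 18 lists at the preset correlation. Of the 14, fry did not call the sarcomere (fry adjusted p = 0.118), calcium handling (0.110), S phase (0.0979), cholesterol (0.0762) and interferon (0.0698) lists, and it called 2 others, given below. For each of the 14 lists the adjusted p with an estimated correlation, given beside its result, was the highest of any alternative tried. The lowest of any alternative ran from 3.3e-15 for the G2 and mitosis list to 0.0202 for the S phase list. List members named to account for counts of 5 or fewer were chosen after their values were seen where they fall outside the naming rule; of 18 called genes named outside it anywhere here, 9 were called without each library in turn.

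Genes of G2, mitosis and cytokinesis fell almost throughout: 37 of 40 were lower and 1 was higher, the same counts as adjusted over the list alone. The median log2 fold change was −1.12 (camera adjusted p = 3.86e-13; adjusted p = 0.625 with an estimated correlation). Mki67, a marker of cycling cells, fell from 88.7 ± 5.34 to 21.9 ± 6.69 CPM (−2.02 ± 0.20 SE), and the kinetochore genes Cenpf and Cenpe fell by 2.04 and 1.52. The riser was Gtse1 (0.59). Of 35 S phase genes, 12 rose and 2 fell (13 and 3 adjusted over the list alone). Their median was 0.199 (95% bootstrap interval over genes −0.003 to 0.411), with a camera adjusted p of 0.0429 (0.732 with an estimated correlation). Among them the replication licensing genes Cdt1 (0.88), Mcm5 (0.87) and Mcm7 (0.58) rose, and Clspn (−0.68) and Uhrf1 (−0.55) fell. The S phase call was lost without Lmna_shRNA replicate 1 (camera adjusted p = 0.109) and without control_pLKO replicate 3 (0.165).

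Of 30 p53 targets and cell cycle inhibitors, 18 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.00126; adjusted p = 0.625 with an estimated correlation). Cdkn1a, the inhibitor p21, rose from 1432 ± 76.0 to 3050 ± 484 CPM (1.09 ± 0.14 SE), and Mdm2, the ubiquitin ligase of p53, rose from 474 ± 13.4 to 950 ± 141 CPM. Sesn2 rose by 1.60 and Perp by 1.10, and the member that fell was Phlda3 (−0.71). Of 26 genes of the integrated stress response, 17 rose and 5 fell (18 and 5 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00575; adjusted p = 0.428 with an estimated correlation). Sesn2 belongs to this list too, and Cebpg rose by 0.71, whereas Pck2 (−1.02), Vldlr (−0.99), Sars (−0.55), Shmt2 (−0.43) and Nupr1 (−0.48) fell. The call of Nupr1 was lost with 1 of 4 libraries left out, at an edgeR adjusted p of up to 0.145 without control_pLKO replicate 1.

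Of 40 genes induced by type I interferon, 27 were lower and 0 higher (30 and 0 adjusted over the list alone), with a median of −0.80 (camera adjusted p = 9.02e-07; adjusted p = 0.732 with an estimated correlation). Ifi44 fell from 177 ± 35.5 to 52.2 ± 13.8 CPM (−1.76 ± 0.21 SE), Sp100, a nuclear body protein, fell from 79.5 ± 18.1 to 28.2 ± 6.13 CPM and Samd9l fell by 1.46. Parp9 fell from 133 ± 12.2 to 66.5 ± 11.1 CPM and overlaps Dtx3l, another member, named for that overlap (−0.57; edgeR adjusted p = 0.0298). The call of Dtx3l was lost with 1 of 4 libraries left out, at an edgeR adjusted p of up to 0.114 (without Lmna_shRNA replicate 1), and its log2 fold change was −0.38 without control_pLKO replicate 3.

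Of 18 hypoxia genes 12 were lower and 0 higher (13 and 0 adjusted over the list alone), with a median of −0.80 (camera adjusted p = 3.53e-05; adjusted p = 0.572 with an estimated correlation). Ndrg1 fell from 185 ± 18.7 to 42.6 ± 3.80 CPM (−2.12 ± 0.12 SE), Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 2.26, Bnip3, a mitophagy receptor, by 2.13 and Egln3, an oxygen-sensing hydroxylase, by 1.70. Of 22 glycolysis genes 14 fell and 1 rose, the same counts as adjusted over the list alone, with a median of −0.59 (camera adjusted p = 0.003; adjusted p = 0.625 with an estimated correlation). Pfkl, a phosphofructokinase, fell by 1.68 and Tpi1, triose phosphate isomerase, by 1.45, and the riser was Ldhb, a lactate dehydrogenase subunit (1.33). Of 21 genes of cholesterol synthesis and uptake 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of −0.41 (camera adjusted p = 0.0163; adjusted p = 0.732 with an estimated correlation). The low-density lipoprotein receptor gene Ldlr fell by 1.68, Nsdhl by 1.55 and Hmgcs1 by 1.07, Hsd17b7 rose by 0.71, and the call was lost without Lmna_shRNA replicate 3 (camera adjusted p = 0.0657).

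Of 35 cardiac sarcomere genes 15 fell and 2 rose (18 and 2 adjusted over the list alone), with a median of −0.997 (camera adjusted p = 0.00195; adjusted p = 0.732 with an estimated correlation). The median was −0.63 without Lmna_shRNA replicate 1 and −0.66 without control_pLKO replicate 2. Actc1, cardiac actin, fell from 407 ± 124 CPM by 2.02 ± 0.36 SE, Tpm1, a tropomyosin, fell from 2232 ± 264 to 900.1 ± 206 CPM, and Tnni1, the slow skeletal troponin I, fell by 1.54. Flnc (0.46) and Cryab (0.41) rose, with an edgeR adjusted p of 0.139 and 0.0761 without control_pLKO replicate 2 and calls also lost without other single libraries. Of 31 genes of calcium handling and excitation 10 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.0264; adjusted p = 0.732 with an estimated correlation). The sodium-calcium exchanger gene Slc8a1 fell by 1.60, the calcium channel gene Cacna1g by 1.23 and the potassium channel gene Kcnh2 by 1.12. Kcnd3 (2.11) and Gja1 (0.32) rose. The call of Gja1 was lost in 5 of 6 fits with 1 library left out (edgeR adjusted p up to 0.167, without Lmna_shRNA replicate 1). The call of the calcium handling list was lost without Lmna_shRNA replicate 1 (camera adjusted p = 0.109) and without control_pLKO replicate 2 (0.0832). Of 30 cardiac transcription factors 11 fell and 3 rose (12 and 3 adjusted over the list alone) and the list did not differ from other genes (median −0.07; camera adjusted p = 0.293). Hand2 fell from 307 ± 22.3 to 144 ± 14.3 CPM (−1.09 ± 0.12 SE), and Tbx20, Zfpm2 and Meis2 fell by 1.13, 1.06 and 1.06. Hey1 was among those that rose (1.23). Among atrial and pacemaker markers 4 of 17 fell, among them Dkk3 (−1.07), and 1 rose, and among ventricular markers 2 of 10 fell, Myh7 (−1.72) and Hand1 (−0.44); neither list passed (camera adjusted p = 0.435 and 0.0973), and their counts were the same adjusted over the list alone.

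Some lists held markers of other cell types that such cultures could contain. Of 18 smooth muscle and pericyte markers 15 fell and 0 rose, the same counts as adjusted over the list alone, with a median of −1.23 (camera adjusted p = 5.46e-07; adjusted p = 0.428 with an estimated correlation). Myh11, the smooth muscle myosin, fell from 66.3 ± 9.60 to 12.7 ± 2.61 CPM (−2.38 ± 0.17 SE), Cspg4 by 2.31, Mcam by 1.89 and Cald1 by 1.56. Of 30 fibroblast and extracellular matrix genes 16 fell and 2 rose (17 and 4 adjusted over the list alone), with a median of −0.46 (camera adjusted p = 0.00195; adjusted p = 0.732 with an estimated correlation). Col6a3 fell from 570 ± 73.6 to 98.2 ± 25.0 CPM (−2.54 ± 0.19 SE), Thy1 fell by 2.97 and Tnc, tenascin C, by 1.14, whereas Fn1 (0.65) and Loxl1 (0.51) rose, with an edgeR adjusted p of up to 0.0965 and 0.159 when 1 library was left out (control_pLKO replicate 1). The calls of Fn1 and Loxl1 were each lost in 4 of 6 fits with 1 library left out. The log2 fold change of Loxl1 was 0.27 without Lmna_shRNA replicate 2. Of 23 endothelial markers 8 fell and 0 rose, the same counts as adjusted over the list alone, with a median of −0.65 (camera adjusted p = 0.003; adjusted p = 0.625 with an estimated correlation). They included Npr3 (−1.47), Egfl7 (−1.35) and Ecscr (−1.13). Of 11 blood and macrophage markers 7 fell and 0 rose, the same counts as adjusted over the list alone, with a median of −0.95 (camera adjusted p = 0.0128; adjusted p = 0.625 with an estimated correlation). They included Adgre1, which encodes F4/80 (−1.65), Ptprc (−1.57) and Csf1r, the receptor of a macrophage growth factor (−1.15). Epicardial and mesothelial markers did not pass as a list (4 of 14 rose and 1 fell, the same adjusted over the list alone; median 0.16; camera adjusted p = 0.376). Krt8 (0.88), Krt18 (0.77) and Wt1, an epicardial transcription factor (0.76), rose and Krt19 fell (−0.75).

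The nuclear lamina and envelope list did not pass: 7 of 26 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.860). Lmna itself is a member and 1 of the 6. The median was 0.03 and the mean −0.11, against a mean of 0.07 for the other 25, and camera put the list up where fry put it down. Tmem201 (1.11), Lemd2 (0.80) and Sun1 (0.77), all of the inner nuclear membrane, rose. Of 25 inflammatory genes 11 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.34; camera adjusted p = 0.145); the chemokine gene Ccl7 (1.11) and the cytokine gene Lif (1.04) rose, and Il1b (−3.05) and Tnfaip2 (−1.16) fell. Of 25 immediate early genes 9 rose and 1 fell (camera adjusted p = 0.0622), with Arc up by 1.27 and Fos by 1.02. Of 28 targets of YAP and SRF 7 rose and 11 fell (camera adjusted p = 0.293), with F3, tissue factor, at 1.72 and Filip1l at −1.21. Of 21 TGF-beta targets 8 fell and 1 rose (camera adjusted p = 0.159; fry adjusted p = 0.0235). Itgb3 (−1.55), Serpine1 (−1.38) and Tgfbi (−1.02) were among those that fell. Of 21 Wnt targets 3 rose, Lgr5 (3.02), Znrf3 (1.29) and Dkk1 (1.12), and 8 fell, among them Nkd1 (−1.38) and Wnt11 (−1.23). Adjusted over the list alone 4 rose and 9 fell, and the median was −0.45 (camera adjusted p = 0.293). Lgr5 was near the floor, at 0.128 CPM with pLKO and 1.10 CPM with Lmna shRNA. In the Notch pathway 4 of 16 rose, among them Lfng (2.15) and Dll1 (1.08), and 3 fell, led by Notch4 (−1.87; camera adjusted p = 0.824), with a median of −0.02 and a mean of 0.09. Unfolded protein response genes split, with 5 of 20 up, led by Herpud1 (0.81), and 5 down, among them Calr (−0.82). Their median was 0.01 and their mean −0.03 (camera adjusted p = 0.913). Of 19 genes of cardiac stress 3 rose and 4 fell (camera adjusted p = 0.824), with the heme oxygenase gene Hmox1 at 0.89 and Ankrd1 at −1.29.

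Of 29 fatty acid oxidation genes 5 rose and 5 fell (camera adjusted p = 0.871), with Pdk4 at 1.08 and Ucp2 at −1.41. Of 56 nuclear genes of oxidative phosphorylation 5 rose and 3 fell (2 and 1 adjusted over the list alone). Their camera adjusted p was 0.663, with Cox5a at 0.65 and Atp5c1 at −1.45. Of 81 ribosomal protein genes 15 rose and 2 fell (10 and 1 adjusted over the list alone). Their camera adjusted p was 0.123, with Rps15a at 1.15 and Rpl4 at −1.13. Reads of ribosomal protein genes may be shared with pseudogenes. Of 13 reference genes 2 rose, among them Tbp (0.62), and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.693). Of 11 pluripotency genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.376), with Dnmt3b at 0.83 and Klf2 at −1.31. Of 12 endoderm markers 2 rose and 1 fell (camera adjusted p = 0.913), of 9 neural markers 1 rose and 2 fell (camera adjusted p = 0.701), and of 4 markers of skeletal muscle and early mesoderm 2 fell, Tnnt3 (−2.16) and Tnni2 (−0.94; camera adjusted p = 0.114; fry adjusted p = 0.0103). The neural marker with the largest fall was Nes (−1.90). Where no other count is given in these last paragraphs, the count adjusted over the list alone was the same. In the endoderm, neural and unfolded protein response lists the direction of fry was opposite to that of camera, and in the cardiac stress list the median (−0.003) and the mean (0.01) differed in sign.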

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

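The use of 1 transcript per gene, and the runs on the longest transcript, on the sum over transcripts and on every transcript, were chosen after the table was seen; the other alternatives here were planned. The direction and call of Lmna held under every alternative (−4.51 to −4.85). For the run on every transcript, this range takes only the Lmna transcript with the highest edgeR adjusted p. With library size only, edgeR called 2884 higher and 2831 lower genes, a share of 50.5% higher against 47.4%, and 5539 calls were shared with the main result. DESeq2 called 2790 and 3100 (5639 shared), and limma-voom 2701 and 3094 (5692 shared). Genes changed by at least 2-fold numbered 1003 at a mean of at least 5 CPM, where 11094 genes were tested. At an adjusted p of 0.01 there were 1432 higher and 1916 lower genes. With every transcript tested on its own there were 5731 higher, 6089 lower and 3306 changed by at least 2-fold, since isoforms count shared reads repeatedly. Leaving out 1 library gave 1665 to 2983 higher genes (1665 without control_pLKO replicate 2), 2231 to 3225 lower genes, 1524 to 2079 changed by at least 2-fold and 12 to 17 lists, with fewer samples in the fit. Without the count filter there were 2746 higher and 3121 lower genes. Of 178 named genes, 2 to 18 lost their call when 1 library was left out and 3 did with DESeq2. Tbx6, which did not pass (−0.05), changed sign: its log2 fold change ran from −0.45 to 0.17 when 1 library was left out, and was 0.08 without Lmna_shRNA replicate 3; the cause was not tested. With an estimated correlation 0 lists passed with camera, and 14 with the preset one; fry called 11, of which 9 were among the 14. Over all genes, deviations of same-numbered libraries gave no sign of pairing (correlations 0.03, 0.10 and −0.33), which does not exclude pairing in some genes. With the number as a block edgeR called 2134 higher and 2709 lower genes, and camera 16 lists. The camera adjusted p then fell for the sarcomere (0.00195 to 4.81e-06), interferon (9.02e-07 to 1.115e-09) and calcium handling (0.0264 to 0.00416) lists, among others. It rose slightly for the G2 and mitosis, p53, hypoxia and smooth muscle lists. Small changes may be missed: in the simulation of this comparison, 26.9% of 1.5-fold changes were called. Those changes were all in genes with a mean of at least 5 CPM, and the part of depth in that share was not tested. Few of the simulated genes were changed, whereas 40.7% of tested genes were called here. The adjusted threshold was therefore stricter in the simulation, and its share of calls does not carry over to these data.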

Other observations

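The tests of the macrophage transcripts, of S phase against G2, and of the base composition of 3' UTR words, the follow-up of the first-ranked word in rising genes, the medians without genes that hold it, the shorter pseudogene matches, the splits list by list and the added gene families were chosen after the results were seen; the other tests here were not. Some families that were not fixed lists themselves stood out among 37 looked at by eye after the data were seen. Of the 37, 35 had at least 3 tested genes and were tested together with camera. Collagen genes such as Col6a3 also belong to the fixed fibroblast and extracellular matrix list, so the fall of collagen chains partly repeats that result. Of 37 collagen chain genes 19 fell and 1 rose (median −0.58; camera adjusted p = 0.00188; adjusted p = 0.638 with an estimated correlation). Of 35 genes whose symbol starts with Adam, mostly membrane and secreted metalloproteases, 22 fell and 2 rose (median −0.58; camera adjusted p = 7.23e-04; adjusted p = 0.638 with an estimated correlation). Of 15 genes of the immunoproteasome, peptide transport and MHC class I, which interferon induces, 10 fell and 0 rose (median −0.60; camera adjusted p = 0.0185; adjusted p = 0.642 with an estimated correlation). Zinc finger genes (361) had 82 risers and 19 that fell (median 0.19; camera adjusted p = 0.00326; adjusted p = 0.638 with an estimated correlation). Of 19 epithelial genes 8 rose and 1 fell (median 0.50; camera adjusted p = 0.038; adjusted p = 0.638 with an estimated correlation), and of 10 histone genes 7 rose and 0 fell, at the same adjusted p (0.642 with an estimated correlation). Subunits of the vacuolar ATPase (9 of 20 rose and 1 fell; camera adjusted p = 0.141) and imprinted genes (3 of 34 rose and 14 fell; camera adjusted p = 0.352) did not pass.

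A hairpin can lower transcripts other than its target through short matches of its seed to their 3' UTRs, and such a match would also occur in the Lmna transcript. Of all 16384 words of 7 bases, AGAAGAA, which occurs in Lmna, was the most enriched in the 3' UTRs of genes lower by at least 2-fold (265 of 1104 genes, 191 expected from genes of like UTR length and GC; z = 6.71; Bonferroni-adjusted p = 1.59e-07), above every word absent from Lmna (highest z 5.49, a word that overlaps it), though 17.1% of all words occur in Lmna. The word was depleted among genes higher by at least 2-fold (z = −5.13). A trend with transcript length and GC was argued against as the whole cause (92.4% of the genes kept a log2 fold change of −1 or less without it). Among words of 5 A and 2 G that share under 5 bases with AGAAGAA, the highest z was 2.65. This argues against that base count alone. Other words of A and G also ranked high, such as GAAGAAG (z = 5.38), which overlaps AGAAGAA, and GAAAGAG (z = 4.51). A wider composition rich in A and G was not tested. Seed matches are thus a candidate explanation for a part of these genes, with an excess well below their number; a different regulator that binds the same word, and the loss of Lmna itself, stay open, since the hairpin's sequence is not given in the sources used here and only 1 hairpin condition was compared.

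The fall of interferon-induced genes may have come from fewer macrophages, from a technical trend or from the knockdown. The 15 abundant macrophage transcripts tested lost 65.0 CPM in sum, which is 3.02% of the 2155 CPM that the interferon list lost. They held 328 CPM with pLKO, so they could not have lost as much as the list, the bound set for that explanation. Much of the sum was Ctsz, which went from 162 to 172 CPM, and Cd74 rose as well (6.63 to 9.43 CPM). The others fell, among them Csf1r from 24.1 to 10.8 CPM and C1qa from 6.99 to 2.82 CPM. The sum therefore cannot decide whether fewer macrophages played a part. After the trend with length and GC was removed, the median of the list was −0.74 (95% bootstrap interval over genes −0.97 to −0.52). That interval treats the list's genes as independent, though their estimated correlation was 0.687, and leaves out the spread between libraries. Without removal of the trend, the median ran from −0.93 to −0.64 when 1 library was left out. Genes with the word AGAAGAA did not carry the fall: the median was −0.83 without them and −0.80 with them. A difference between the vectors or in the response to the virus was not tested. Like fewer macrophages, it stays open beside the loss of Lmna.

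Gapdh (2.32 CPM over the 6 libraries) and Ppia (1.69 CPM), which are abundant in most cells, lay near the floor of the count table, and no biological explanation was tested. Of reads shared with processed pseudogenes the counts of copies speak both ways: Gapdh has 66 near-identical copies over at least 50% of its transcript, but Ppia, Hprt (0.668 CPM), Cycs (1.77 CPM) and Pgam1 (3.83 CPM) have 0, and Eef1a1 with 7 had 1378 CPM. Shorter near-identical matches to 18 pseudogenes were found for Ppia and to 0 for Hprt. Over 82 ribosomal protein genes the Spearman correlation across genes of the number of copies with the mean CPM was −0.198 (permutation p = 0.0751, two-sided; genes are not independent replicates), between the bounds set for and against the explanation. It stays open for Gapdh, and no copy found here supports it for Hprt.

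Fewer cycling cells of every phase would have lowered S phase genes with the G2 and mitosis genes. The S phase median was 0.199, which was above the bound set for that explanation. Its 95% bootstrap interval over genes (−0.003 to 0.411) treats the genes as independent, though their estimated correlation was 0.220. It leaves out the spread between libraries. The median ran from 0.18 to 0.28 when 1 library was left out. Genes that rose did not, by their median, lie in gene-poor regions. Their median number of protein-coding genes within 500 kb was 16, against 14 for matched genes that did not pass (114%). The 95% bootstrap interval over genes was 100 to 114%. It treats genes as independent, though genes near each other share neighbours. For genes that fell the share was 92.9% (80 to 93.3%).

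The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2752 higher, 3060 lower and 1749 genes changed by at least 2-fold. The highest of the other splits gave 0 of each, so 1 of the 10 splits gave as many. Every other split puts libraries of both groups on each side, so a group difference widens the spread within its sides. Its lack of calls is therefore no measure of chance. For the list tests 4 of the 10 splits called at least as many lists as the real one, 14, with 18 in the highest of the others. Calls of camera at the preset correlation therefore say little of the groups by their number alone. The other splits also keep a part of the group difference, so their lists are not a measure of chance alone. By list, the real split had the smallest adjusted p of the 10 for the integrated stress response, glycolysis, hypoxia and smooth muscle lists, while another split had a smaller one for each of the other 10 lists called, among them G2 and mitosis (3.04e-14), interferon (4.63e-19), sarcomere (1.29e-12) and p53 (7.61e-04) genes.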
